A study of Mus musculus with 6 samples.

How the data were processed

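Per the labels, total RNA was sequenced from group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that lack rearranged antigen receptors and make type 2 cytokines. The cells came from the lungs of 8-week-old C57BL/6J mice that carried a green fluorescent IL-10 reporter. Per the labels' protocols, mice received 3 intranasal doses of recombinant IL-33 (0.5 µg each), an alarmin cytokine that activates ILC2s. Sorted ILC2s were cultured for 48 h with IL-2, IL-7 and IL-4 at 10 ng/mL each and were then sorted again into IL-10-producing and IL-10-negative cells. Libraries were made from 10 ng of RNA, and the selection of transcripts was not given in the sources used here. Each population had 3 libraries. The labels do not say whether these came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

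Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.5.3a and Partek were used with genome build mm10. The authors deposited a table of estimated counts per gene, not normalized between libraries, in which 50.4% of the values were not whole numbers. It held 21017 genes, and the smallest total of a gene over the 6 libraries was 10. The authors also deposited a table of normalized signal values for 13824 genes. All of its values (100% within a tolerance of 1%) equalled the estimated count plus 1 times a single factor per library, and the 75th percentile of each library lay between 53.03 and 53.06. The annotation release was not given in the sources used here. Of the genes, 19917 had the same versioned identifier in GENCODE M21, and all of these had the same chromosome, start and end on GRCm38 (mm10) once 1 was subtracted from the listed stop. Positions below are 1-based and come from the deposited table. Whether the counting used strand was not given in the sources used here, so values of genes that overlap a neighbour or an antisense gene are uncertain. The same holds for near-identical families such as the T-cell receptor constant genes, the Ly49 receptors and the granzymes.

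Library totals ran from 47012941 to 69511433 counts. The estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. TMM factors were used, the group was the only term, and filterByExpr kept 16654 genes at its defaults (minimum count 10, minimum total 15). P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, and every gene-level adjusted p below comes from this test. A second count asked for a change of at least 2-fold. Levels are CPM scaled with the TMM factors, given as mean ± SD over 3 libraries, and log2 fold changes are IL-10-producing over IL-10-negative. Pairs of libraries within a group differed by 2.39 to 2.96 times the Poisson expectation (median over genes with a summed count of at least 20), so no library was a copy of another and all 6 were used. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

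A total of 20 gene lists and 10 marker lists of other cell types were fixed before the data were examined. Of 586 list genes 12, and of 132 marker genes 25, had no row in the count table. Each list was tested with camera (limma 3.58.1), a competitive test against all other genes, on log CPM with a preset inter-gene correlation of 0.01, adjusted over the 20 or the 10 lists. Beside it, the correlation was estimated per list, and fry, a rotation test of whether a list's genes moved on balance in a single direction, was run. The rule for named genes was also fixed beforehand. It took Il10, Prdm1, Maf, Gata3, Il5 and Il13. It added the 8 largest changes in each direction among genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, without unnamed gene models. By chance, 10% of genes show no overlap with 3 libraries against 3. It also took, from each list that passed camera or had at least 2 changed members, the 4 members with the smallest p, which gave 126 genes in all. Results of some of these genes are not reported here. Shares of the counts were compared by a two-sided exact permutation test, which with 3 against 3 libraries cannot go below 0.1.

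Alternatives were DESeq2 size factors, library size only, no filter on low counts, at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2 of the authors' normalized values plus 1, the replicate number as a block, and leaving out each library. Added after the data had been opened were a test against a change of 1.2-fold (glmTreat) and a correction for GC content and transcript length. The correction fitted smooth terms per library on 16642 genes (99.93% of those tested), with values from the longest GENCODE M21 transcript, and its offsets were centred in each library. That centring was added after a first version without it had moved the median log2 fold change of all genes to 0.053, with 6588 genes changed (4536 higher), against 6025 (3067 higher) with centring.

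The scripts were tested on simulated counts for 16654 genes drawn from the real means, library sizes and dispersions of this comparison. Changed genes were drawn from those with a mean of at least 5 CPM, so recovery below that level was not tested. In sets of 50 changed genes each, 88% of changes of 1.2-fold were recovered, and 100% at 1.5-fold, 2-fold and 4-fold. Of all calls, 3% were false, with far fewer genes changed than the 35.69% in the data. A list raised 1.2-fold, also of genes of at least 5 CPM, was found and 0 of 20 unchanged lists were called. Simulated genes were drawn independently of one another. The list calls were therefore not tested with correlated genes, which the data may hold. A simulated GC trend, with no gene changed, gave 6958 calls before and 0 after the correction. The trend followed the same GC values that the correction fits, so other biases and the retention of true changes were not tested.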

Results

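Gene expression was measured by RNA sequencing in 6 libraries of mouse lung ILC2s, 3 from cells that produced IL-10 and 3 from IL-10-negative cells, sorted apart after the same culture protocol. The IL-10-producing libraries held 54483205, 69511433 and 47012941 counts, and the IL-10-negative libraries 51218587, 57989729 and 55788603. The number of genes with a count ran from 20221 to 20576 per library. The design holds a single comparison, which asks how the transcriptome of ILC2s that make the anti-inflammatory cytokine IL-10 differs from that of ILC2s that do not.

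Il10 itself (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974) stood at 848 ± 7.78 CPM in IL-10-producing and 13.5 ± 0.608 CPM in IL-10-negative libraries (SD, n = 3), a 62.6-fold difference (log2 fold change 5.97, SE 0.028, adjusted p = 2.38e-36). The cells were sorted on the reporter of this gene, so the value checks the labels and is no finding between the populations. Prdm1, which encodes the transcription factor Blimp-1 (ENSMUSG00000038151.13, chromosome 10, 44437177 to 44528501), was higher in IL-10-producing cells, at 193 ± 2.43 against 169 ± 4.22 CPM (log2 fold change 0.19, adjusted p = 3.1e-07). Maf, which encodes c-Maf, another factor linked to Il10 in lymphocytes (ENSMUSG00000055435.6, chromosome 8, 115682942 to 115707794), did not pass the test, with 396 ± 11.1 against 397 ± 8.29 CPM (adjusted p = 0.918). Gata3, the lineage factor of ILC2s (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), fell from 832 ± 12 to 708 ± 11.3 CPM (log2 fold change -0.23, SE 0.0181). The type 2 cytokine gene Il13 (ENSMUSG00000020383.1, chromosome 11, 53631324 to 53634702) fell from 1101 ± 15 to 968 ± 35.7 CPM. Il5 (ENSMUSG00000036117.2, chromosome 11, 53720794 to 53725106) was 1.04-fold higher, at 2155 ± 26.4 against 2078 ± 20.7 CPM (adjusted p = 0.0103). The Il5 call was lost with library size only (adjusted p = 0.288), after the GC and length correction (0.128) and without IL-10-negative replicate 3 (0.0655).

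**Figure D1:**
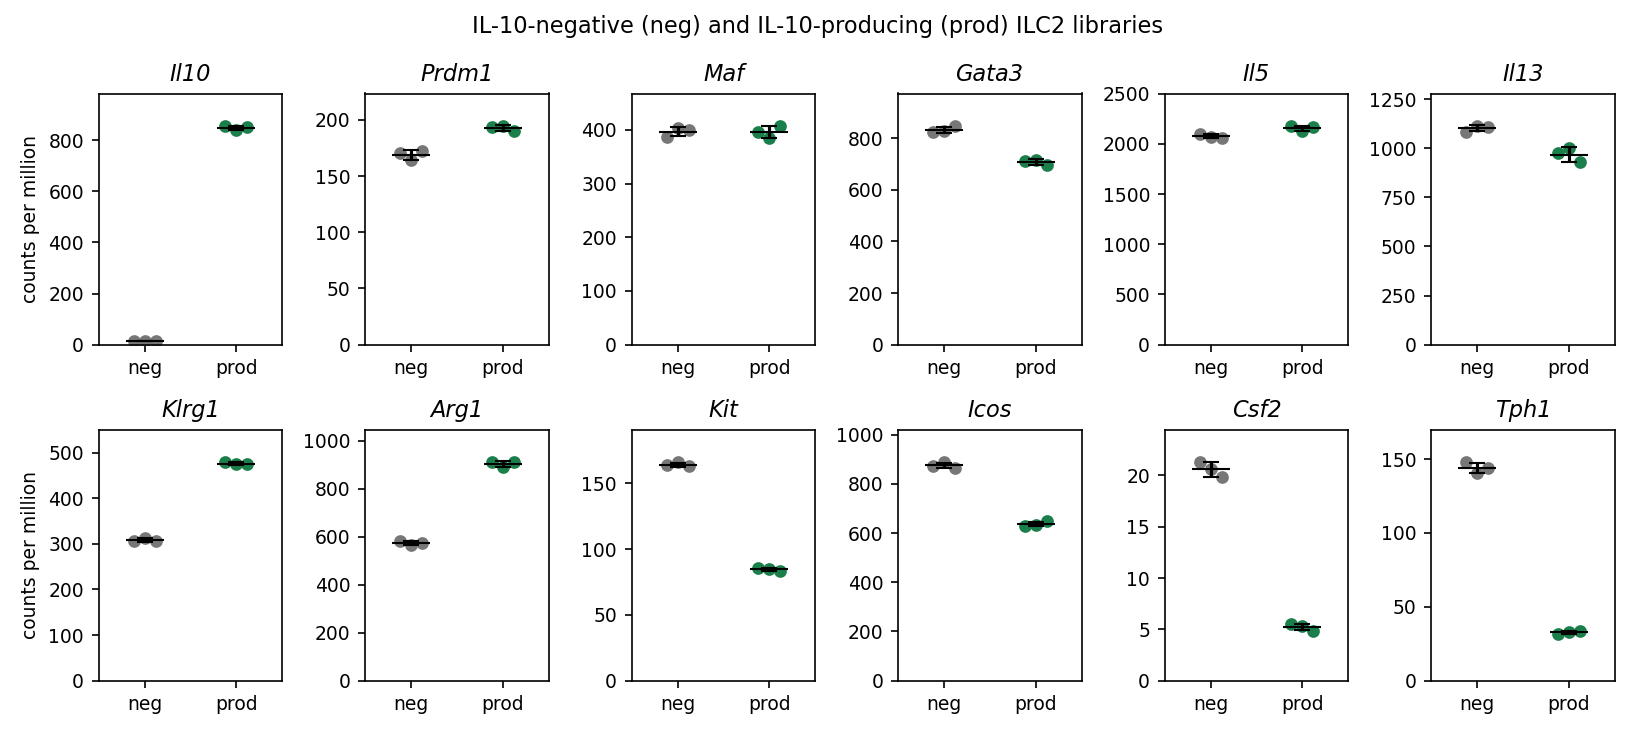
CPM (linear axes from 0) of 12 genes in each IL-10-negative (neg, grey) and IL-10-producing (prod, green) library; points are libraries, and bars give the mean and SD of 3. Il10 stood at 13.5 against 848 CPM, and the 3 libraries of a group lay close together in all 12 panels.

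Many genes differed between the populations, most of them by little. Of 16654 genes tested, 5943 changed (35.69%), 2840 higher and 3103 lower in IL-10-producing cells. Their median absolute log2 fold change was 0.224, and 4644 of them changed by less than 0.5 on the log2 scale. At least 2-fold changes were fewer and mostly downward, with 123 genes higher and 487 lower, and 491 of these 610 genes stayed under 5 CPM in the higher group. With library size only, 6000 genes changed, of which 36.8% were higher, against 47.8% with TMM. Among log2 values of the authors' normalized table the 2-fold count was 139, with a filter of 50 counts in 3 libraries it was 298, and a test against a change of 1.2-fold kept 1317 genes.

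**Figure D2:**
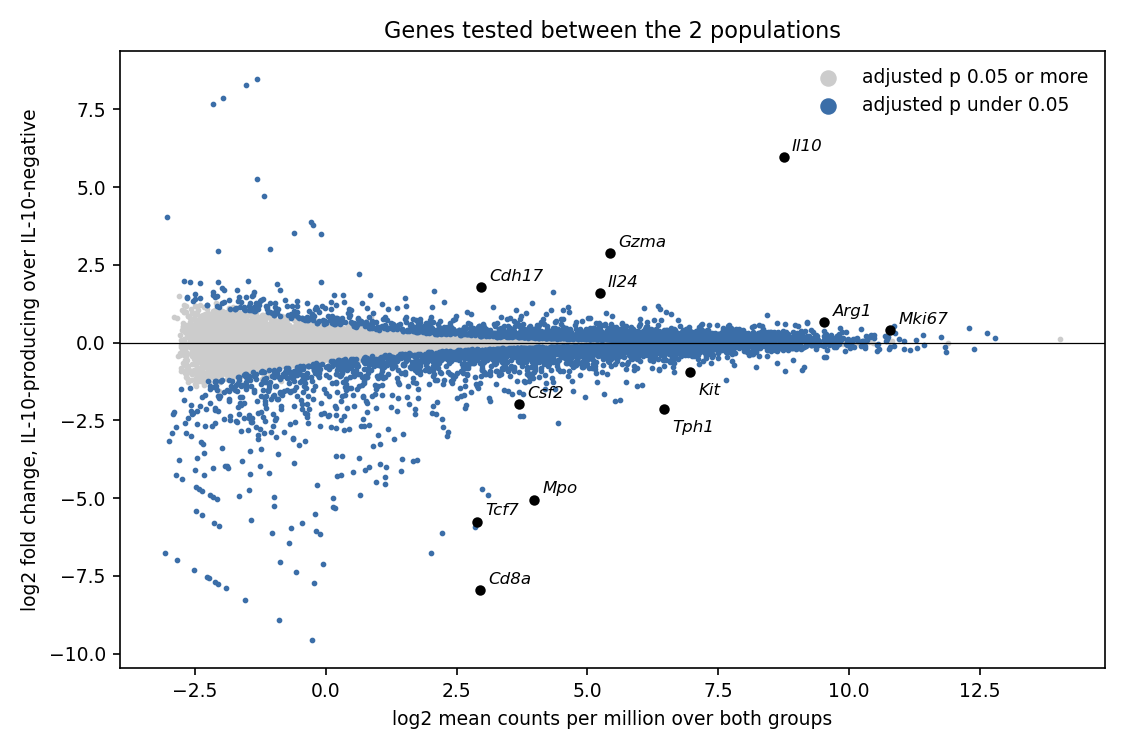
Log2 fold change of each tested gene (IL-10-producing over IL-10-negative) against the log2 of its mean CPM over both groups; blue points have an adjusted p under 0.05, and fitted values of genes at 0 in a group depend on the prior count. Il10 lies apart at 5.97, while large downward changes such as Cd8a (-7.96) gather among genes of low CPM.

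After Il10, the gene with the largest rise under the naming rule was Gzma, the cytotoxic protease granzyme A (ENSMUSG00000023132.8, chromosome 13, 113093825 to 113100981), at 76.0 ± 6.51 against 10.3 ± 0.893 CPM, 7.36-fold higher. Cdh17, a cadherin, rose 3.46-fold to 12.2 ± 1.01 CPM. Il24, a cytokine of the IL-10 family whose gene lies 132.4 kb from Il10 (chromosome 1, 130882074 to 130887454), rose 3.03-fold to 56.7 ± 1.56 CPM. Gem, a small GTPase, rose 3.09-fold, and Igkc, Ngef and Akap6 rose 3.17-fold, 2.45-fold and 2.42-fold, reaching 6.38, 6.82 and 21.7 CPM. Among the 8 largest falls were those of Cd8a, Cd8b1, Slfn1, Ms4a4b, Tcf7, Mpo and Ms4a6b, which stood between 8.02 and 30.6 CPM in IL-10-negative cells and below 1 CPM in IL-10-producing cells. Cd8a and Cd8b1 encode the CD8 co-receptor of T cells, and Mpo encodes the myeloperoxidase of neutrophils. Cd8a (chromosome 6, 71373427 to 71379173) had 2550 counts in the 3 IL-10-negative and 10 in the 3 IL-10-producing libraries, a ratio of 259 with an exact 95% counting interval of 140 to 540.

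Genes that mark ILC2s went both ways. Of 23 tested members of the ILC2 identity list, 6 rose and 13 fell (median log2 fold change -0.17, camera adjusted p = 0.0108, and adjusted p = 0.0833 with an estimated correlation). Arg1, which encodes arginase 1, rose from 573 ± 6.91 to 903 ± 11.5 CPM, and Klrg1, an inhibitory receptor found on activated ILC2s, rose from 309 ± 3.71 to 476 ± 2.40 CPM. Kit, the stem cell factor receptor, fell from 164 ± 1.62 to 84.6 ± 1.02 CPM, and Tcf7, the transcription factor TCF-1, from 14.5 ± 0.860 to 0.262 ± 0.141 CPM. Inhibitory and activating surface receptors were mostly lower, with 3 of 26 higher and 17 lower (median -0.45, camera adjusted p = 7.78e-06), or 4 and 17 when adjusted over the list alone. Icos, a costimulatory receptor, fell by 0.46 on the log2 scale to 637 ± 9.83 CPM, Lilrb4a by 0.67 and Klrb1b by 2.00. The 3 that rose with adjustment over all genes were Klrg1, Ctla4 (41.1 ± 0.3 against 23.6 ± 1.62 CPM) and Tigit (43 ± 1.36 against 34 ± 2.54 CPM). Pdcd1 and Havcr2 were among the 17 that fell. Of 30 cytokine receptor and SOCS genes, 6 rose and 17 fell (19 fell when adjusted over the list alone; median -0.13, camera adjusted p = 0.00362, and adjusted p = 0.0663 with an estimated correlation). Il2ra, the high-affinity IL-2 receptor chain, rose from 4206 ± 38.7 to 5835 ± 47.4 CPM and Il1r2, the IL-1 decoy receptor, from 242 ± 5.19 to 445 ± 3.92 CPM. Ifngr1 fell from 96.3 ± 0.363 to 54.5 ± 1.73 CPM and Il18r1 from 26.2 ± 0.937 to 10.8 ± 0.535 CPM. Markers of T cells and of mast cells and basophils were also lower in the IL-10-producing libraries, as given further on.

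Effector cytokine genes other than Il10 were mostly lower in the IL-10-producing libraries. In the list of type 2 and other effector cytokines, 4 of 20 members rose and 13 fell (median -0.31, camera adjusted p = 0.000353, and adjusted p = 0.0663 with an estimated correlation). Csf2, which encodes GM-CSF, fell from 20.6 ± 0.719 to 5.24 ± 0.325 CPM, Il6 from 30.6 ± 0.521 to 10.9 ± 0.426 CPM, Il9 from 8.94 to 1.09 CPM and Tnfsf8, the CD30 ligand, from 17.8 ± 0.991 to 5.70 ± 0.127 CPM. The 4 members that rose were Lif (547 ± 16.9 against 438 ± 3.49 CPM), Tgfb1 (634 ± 3.1 against 570 ± 1.3 CPM), Penk and Il5. Areg, Osm and Tnfsf9 did not pass. The summed CPM of the list, dominated by Il5 and Il13, was 4663 ± 42.2 against 4651 ± 9.82. Of 10 chemokine genes 8 fell and 0 rose (median -1.46, camera adjusted p = 0.000359, and adjusted p = 0.0833 with an estimated correlation). Only Cxcl3 among these was at or above 5 CPM in both groups, and it fell from 107 ± 2.76 to 58.9 ± 3.44 CPM, while Ccl9, Ccl24 and Ccl6 fell from under 3.5 CPM. Among 14 cytotoxic effector genes 5 rose and 8 fell, and the list did not pass camera (median -0.41, adjusted p = 0.108). It passed, as lower, without IL-10-negative replicate 3 (0.0434) and without IL-10-producing replicate 1 (0.0388) or 3 (0.0407). Gzma and Gzmb (74.8 ± 0.878 against 52.0 ± 0.338 CPM) rose, whereas Serpina3g, a serine protease inhibitor, fell from 77.2 ± 1.74 to 21.5 ± 0.821 CPM, and Nkg7 fell from 3.72 ± 0.254 CPM. Markers of T cells (summed level 124 against 213 CPM) and of granulocytes, basophils and mast cells (28.6 against 84.1 CPM) were lower in the same libraries.

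Regulators linked to Il10 in lymphocytes did not move together. Of 25 genes, 9 rose and 9 fell (10 fell when adjusted over the list alone), with a median of 0.01, a mean of -0.57 and a camera adjusted p of 0.865. The sign of the median turned with library size only (-0.02). Nfil3, a basic leucine zipper factor, rose from 279 ± 3.38 to 356 ± 5.68 CPM. The falls with the smallest p were in genes of low level: Eomes went from 3.07 ± 0.341 to 0.0971 ± 0.0302 CPM, Bach2 from 5.45 ± 0.312 to 1.12 ± 0.102 CPM, and Foxp3, the lineage factor of regulatory T cells, from 6.91 ± 0.516 to 1.82 ± 0.212 CPM. T-cell markers were lower in the same libraries.

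Cell-cycle genes were higher in IL-10-producing cells almost without exception. In the mitosis list 39 of 40 genes rose and 0 fell (median 0.32, camera adjusted p = 3.74e-21), and in the list of S phase and DNA replication 37 of 40 rose and 0 fell (38 rose when adjusted over the list alone; median 0.19, camera adjusted p = 7.01e-15). Both calls held with an estimated correlation (adjusted p = 0.0109 for each). Mki67, the proliferation marker Ki-67, rose from 1517 ± 8.32 to 2009 ± 28.4 CPM, Aurka, a mitotic kinase, from 80.7 ± 0.413 to 113 ± 1.02 CPM, and Rrm2, a subunit of ribonucleotide reductase, from 529 ± 0.579 to 708 ± 4.92 CPM. Ccna2, Cenpe, Rrm1, Dut and Hells rose by 0.31 to 0.42 on the log2 scale. In the same libraries, summed markers stood at 124 against 213 CPM for T cells and at 28.6 against 84.1 CPM for granulocytes, basophils and mast cells.

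Among metabolic lists, cholesterol and fatty acid synthesis was higher whether the correlation was preset or estimated, and glycolysis with the preset correlation only. Of 23 glycolysis genes 18 rose and 1 fell (19 rose when adjusted over the list alone; median 0.25, camera adjusted p = 1.23e-08, and adjusted p = 0.102 with an estimated correlation). Tpi1, an enzyme of the pathway, rose from 371 ± 3.50 to 485 ± 6.09 CPM, Ldha, lactate dehydrogenase A, from 1672 ± 11.3 to 2088 ± 55.4 CPM, and Slc16a3, a lactate transporter, from 117 ± 1.90 to 164 ± 5.11 CPM. In cholesterol and fatty acid synthesis 29 of 34 genes rose and 0 fell (median 0.23, camera adjusted p = 2.25e-11, and adjusted p = 0.0231 with an estimated correlation). Scd2, a fatty acid desaturase, rose from 251 ± 3.43 to 370 ± 3.76 CPM, and Cyp51, an enzyme of sterol synthesis, rose by 0.32 on the log2 scale. Nuclear genes of oxidative phosphorylation differed by little, with 14 of 53 higher and 2 lower (median 0.04, camera adjusted p = 0.0108, and adjusted p = 0.398 with an estimated correlation); the call was also lost with library size only (adjusted p = 0.0978) and after the GC and length correction (0.363). Atp5b, a subunit of ATP synthase, rose from 962 ± 10.9 to 1053 ± 13.7 CPM. Fatty acid oxidation (9 of 31 higher, 5 lower; 13 and 5 when adjusted over the list alone; median 0.08, camera adjusted p = 0.0707) and the tricarboxylic acid cycle (6 of 24 higher, 3 lower; 7 and 4 when adjusted over the list alone; median 0.04, camera adjusted p = 0.3) did not pass. Hadh, which acts in fatty acid oxidation, rose from 81.7 ± 1.82 to 108 ± 1.56 CPM, and Sdhd and Mdh2 of the tricarboxylic acid cycle rose by 0.17 and 0.12 on the log2 scale. Amino acid transport and one-carbon metabolism did not pass either, with 10 of 24 higher and 5 lower and a camera adjusted p of 0.193. Its median was 0.06 and its mean -0.055, and it holds Tph1, tryptophan hydroxylase 1, which fell from 144 ± 3.52 to 32.8 ± 0.999 CPM (chromosome 7, 46644641 to 46672537). Slc3a2, the heavy chain of amino acid transporters, fell from 395 ± 6.85 to 295 ± 2.49 CPM. The lower markers of T cells (median -2.67) and of granulocytes, basophils and mast cells (-2.37) stand beside these lists as well.

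**Figure D3:**
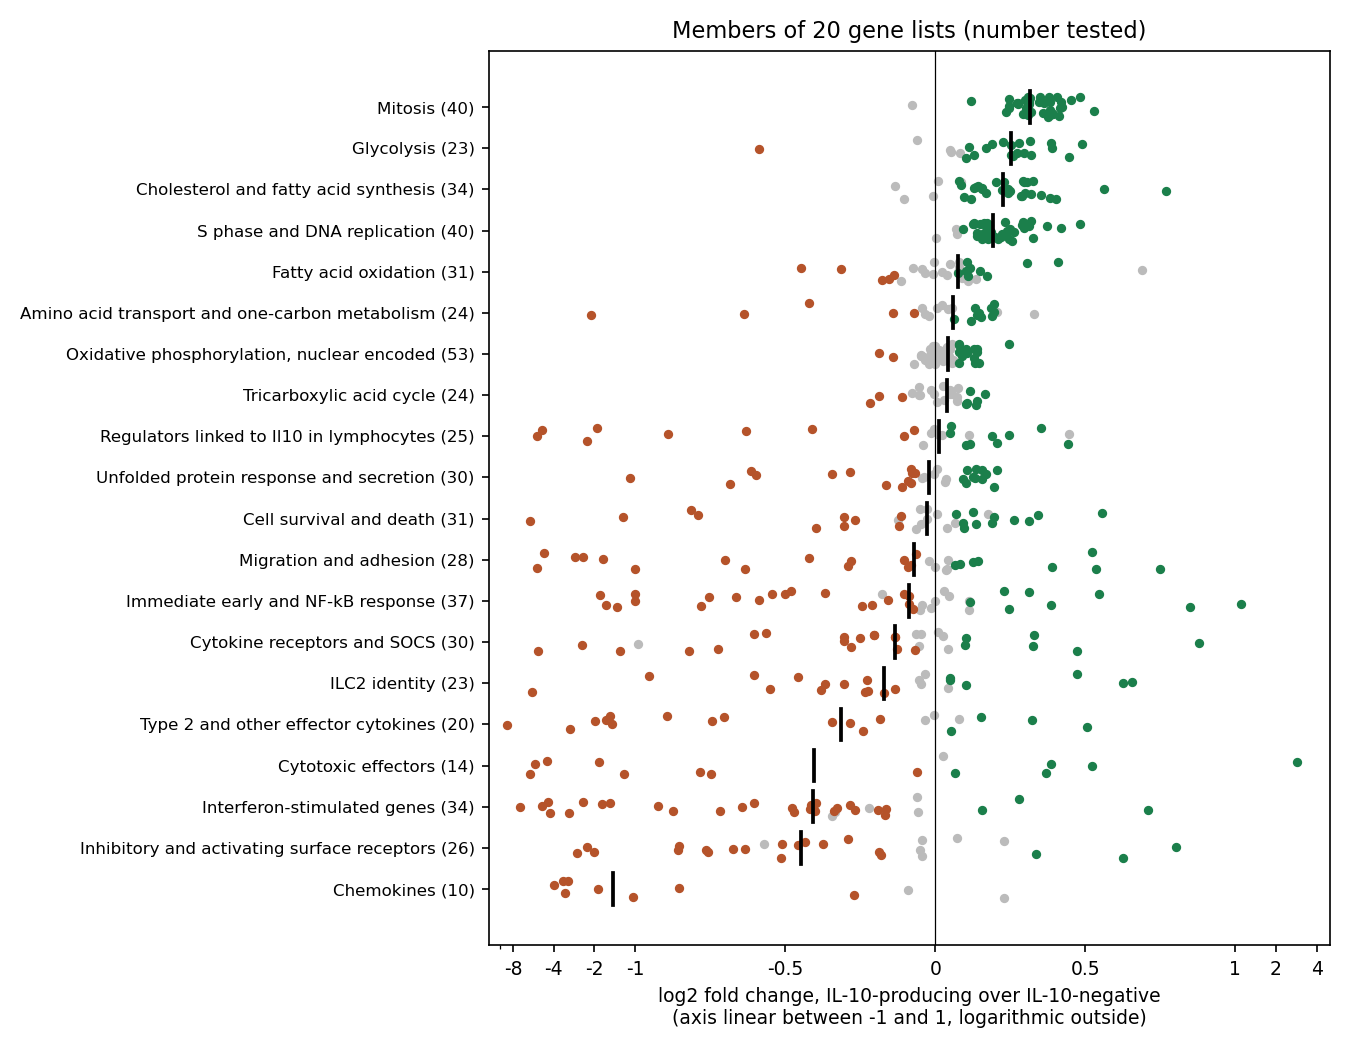
Log2 fold changes (IL-10-producing over IL-10-negative) of the tested members of 20 gene lists, ordered by their median (black bar); green and orange points rose and fell at an adjusted p under 0.05, grey points did not pass, and the axis is linear between -1 and 1 and logarithmic outside. Mitosis (median 0.32) and S phase (0.19) members lie almost all to the right of 0, and chemokines (-1.46) mostly to the left.

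Interferon-stimulated genes were lower in the IL-10-producing libraries. Of 34 tested, 3 rose and 26 fell (28 fell when adjusted over the list alone; median -0.41, camera adjusted p = 2.63e-11, and adjusted p = 0.0162 with an estimated correlation). Among the guanylate-binding proteins and related GTPases, Gbp2 fell from 13.4 ± 0.747 to 3.95 ± 0.336 CPM, Gbp7 from 32.7 ± 1.10 to 17.2 ± 0.522 CPM and Igtp from 55.5 ± 0.959 to 40 ± 1.13 CPM. Ly6e, the most abundant of the 4 named members, fell from 1067 ± 13.3 to 887 ± 12.3 CPM. Some of the largest falls on the log2 scale were in members of low level, such as Iigp1 (0.00487 ± 0.00843 against 1.09 ± 0.173 CPM) and Ifit3 (0.0328 ± 0.0222 against 0.704 ± 0.0842 CPM). The medians of the markers of T cells (-2.67) and of granulocytes, basophils and mast cells (-2.37) were lower in these libraries too.

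The immediate early and NF-kB list held members that went opposite ways, with 8 of 37 higher and 20 lower (9 and 21 when adjusted over the list alone; median -0.09, camera adjusted p = 0.0227, and adjusted p = 0.277 with an estimated correlation). The immediate early factors Egr1 and Fos rose, from 42.8 ± 0.802 to 92.1 ± 3.27 CPM and from 31.5 ± 0.650 to 56.7 ± 2.31 CPM. Tnfaip3, an inhibitor of NF-kB signalling, and Nfkb2, an NF-kB subunit, fell by 0.78 and 0.54 on the log2 scale. The list was not past the threshold after the GC and length correction (adjusted p = 0.058) or with the replicate number as a block (adjusted p = 0.0542). T-cell markers (median -2.67) and those of granulocytes, basophils and mast cells (-2.37) were lower in the same libraries.

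No balance in a single direction passed camera for cell survival and death (11 of 31 higher, 10 lower; 11 and 13 when adjusted over the list alone; median -0.03, adjusted p = 0.924), for the unfolded protein response and secretion (11 of 30 higher, 13 lower; median -0.02, adjusted p = 0.682) or for migration and adhesion (8 of 28 higher, 15 lower; median -0.07, adjusted p = 0.116). The median of cell survival and death turned positive after the GC and length correction (0.01). Single members changed clearly. The anti-apoptotic gene Bcl2 fell from 126 ± 1.77 to 73.1 ± 0.878 CPM, and its pro-apoptotic antagonist Bcl2l11 from 19.3 ± 1.29 to 8.27 ± 0.514 CPM, while Ripk3, a kinase of necroptosis, rose by 0.34 on the log2 scale. Ern1, the stress sensor IRE1, fell from 178 ± 1.76 to 118 ± 1.56 CPM, and Hsp90b1, an endoplasmic reticulum chaperone, rose from 1540 ± 19.7 to 1775 ± 6.28 CPM. The integrin gene Itga4 rose from 168 ± 5.29 to 243 ± 5.73 CPM, Itgb1 fell from 66.9 ± 1.71 to 43.1 ± 1.63 CPM, and Ptger4, a prostaglandin E2 receptor, fell from 57.3 ± 2.52 to 35.3 ± 0.834 CPM. For 10 of the 20 lists the counts adjusted over the list alone equalled those over all genes.

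Markers of T cells were lower in the IL-10-producing libraries throughout. All 14 fell (median -2.67, camera adjusted p = 1.81e-13, and adjusted p = 0.0123 with an estimated correlation), and their summed level was 124 ± 0.666 against 213 ± 3.50 CPM. Cd3e and Cd3d, subunits of the T-cell receptor complex, fell from 8.19 ± 0.283 to 1.25 ± 0.0789 CPM and from 6.21 ± 0.342 to 0.450 ± 0.0216 CPM. Of the 14 markers, 3 were at or above 5 CPM in IL-10-producing cells as well, and 1 is in another list. Markers of granulocytes, basophils and mast cells were lower too, with 11 of 13 falling and 1 rising (median -2.37, camera adjusted p = 1.31e-07, and adjusted p = 0.0207 with an estimated correlation) and a summed level of 28.6 ± 1.55 against 84.1 ± 2.64 CPM. The mast cell protease genes Cpa3 and Cma1 fell from 22.9 ± 1.58 to 4.46 ± 0.549 CPM and from 22.1 ± 1.09 to 4.26 ± 0.427 CPM, and the basophil protease gene Mcpt8 from 10.3 ± 0.420 to 2.39 ± 0.249 CPM.

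Other marker lists moved less clearly. Dendritic cell markers were lower, with 5 of 9 falling (7 when adjusted over the list alone; median -0.56, camera adjusted p = 0.0121, and adjusted p = 0.13 with an estimated correlation), among them Cd74, the invariant chain, from 13.4 ± 0.450 to 7.40 ± 0.657 CPM. Of 4 tested ILC3 markers 3 fell (4 when adjusted over the list alone; median -1.27, camera adjusted p = 0.0152, and adjusted p = 0.17 with an estimated correlation), led by Lta, which fell from 16.6 ± 0.688 to 5.66 ± 0.544 CPM; the call was lost without IL-10-negative replicate 2 (0.166) or 3 (0.13). B-cell markers were mixed (3 of 12 higher, 7 lower, median -0.81, camera adjusted p = 0.307), with Igkc and Ighm higher and Cd37 lower. Among 7 tested markers of NK cells and ILC1, 3 rose, led by Gzma, and 4 fell, with a fitted median of -4.91 (-3.11 with the gene at 0 in a group set to a bound of 3 counts per library) and a camera adjusted p of 0.399. Macrophage and monocyte markers (2 of 9 higher, 5 lower, median -0.12, adjusted p = 0.307), epithelial markers (0 of 5 higher, 2 lower, median -0.25, adjusted p = 0.156), endothelial and fibroblast markers (1 of 4 higher, 0 lower, median 0.17, adjusted p = 0.267) and erythroid markers (0 of 2 higher, 2 lower, median -2.11, adjusted p = 0.0869) did not pass camera. The erythroid list passed, as lower, without any of 5 libraries in turn, with adjusted p from 0.00295 to 0.0273. It did not pass without IL-10-negative replicate 2 (0.252).

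**Figure D4:**
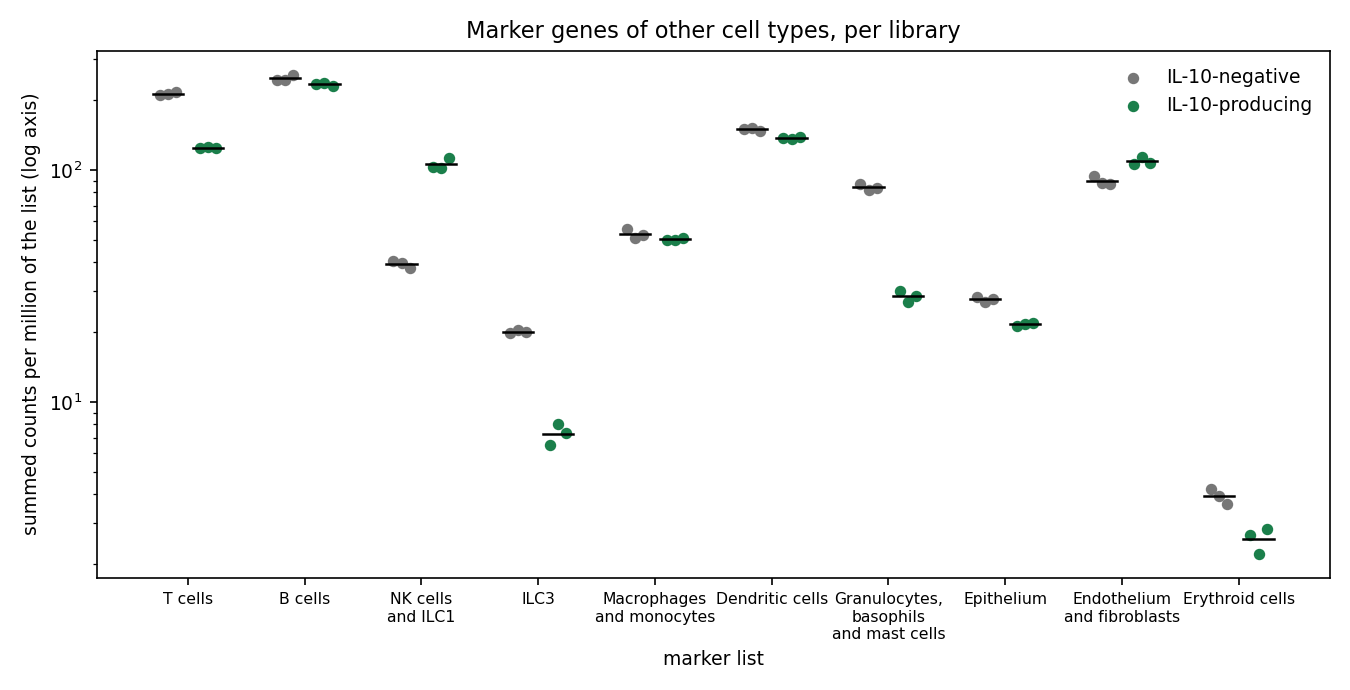
Summed CPM (log axis) of 10 marker lists in each IL-10-negative (grey) and IL-10-producing (green) library; bars are the mean of 3 libraries. T-cell markers stood at 213 against 124 CPM and those of granulocytes, basophils and mast cells at 84.1 against 28.6 CPM.

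Shares of several RNA classes among the counts were compared as well. Ribosomal protein genes took 2.25% ± 0.00917 of the counts in IL-10-negative and 2.21% ± 0.0668 in IL-10-producing libraries (SD, n = 3, exact permutation p = 0.5), and the 10 most abundant genes took 5.70% ± 0.0480 and 5.93% ± 0.429 (exact permutation p = 0.4). Messenger RNAs of the mitochondrial genome took 1.01% ± 0.0313 and 0.963% ± 0.0295 (exact permutation p = 0.2). Mitochondrial ribosomal RNAs took 0.200% ± 0.00606 and 0.290% ± 0.0103, a ratio of 1.45, with all 3 IL-10-producing libraries above all 3 IL-10-negative libraries (two-sided exact permutation p = 0.1, the smallest this design allows).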

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

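The 1.2-fold test and the GC and length correction were added after the data had been opened, and the centring of the correction after its first result (6588 changed genes without it). The number of changed genes lay between 5232 and 6025 under all alternatives except the test against 1.2-fold (1317). Without each library in turn it was 5232 to 5519, and the 2-fold count 609 to 644. The 2-fold count rose to 798 with no filter on low counts (580 shared with the 610). It fell to 298 of 13257 genes tested with at least 50 counts in 3 libraries, and to 139 of 13824 on the authors' normalized values. All 298 and all 139 were among the 610. Both settings tested fewer genes than the 16654 of the main fit, and how much of the fall this explains was not tested. The log2 fold change of Il10 stayed between 5.84 and 6.01.

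Camera calls held under most alternatives. With an estimated correlation, adjusted p rose to 0.0833 for chemokines and ILC2 identity, 0.0663 for type 2 cytokines and for cytokine receptors, 0.102 for glycolysis, 0.277 for the immediate early list, 0.398 for oxidative phosphorylation, 0.13 for dendritic cells and 0.17 for ILC3. Fry, which compares no list with other genes, called all 20 gene lists, among them survival (0.0371), cytotoxic effectors (1.6e-05), fatty acid oxidation (0.000345), migration (2.05e-05), regulators (0.000338), the tricarboxylic acid cycle (0.0137) and the unfolded protein response (5.54e-05). It gave amino acid transport as lower (0.00154), opposite to camera; the list's median and mean differ in sign. It also called endothelium (0.0198), epithelium (0.000386), erythroid cells (0.0053), macrophages (0.0101) and NK cells (0.0117). The stricter filter and the authors' values turned B cells (0.274 and 0.835) and macrophages (0.483 and 0.999) to higher, with no call, and took ILC3 to 0.0738 and 0.0565; the cause was not tested. Oxidative phosphorylation was lost with library size only (0.0978) and after the GC and length correction (0.363), which also took the immediate early list to 0.058 and turned, with no call, cell survival (0.959), the regulators (0.775) and Maf (log2 fold change 0.03); the cause was not tested. Leaving out single libraries gave 0.0388 to 0.125 for cytotoxic effectors, 0.00295 to 0.252 for erythroid cells, 0.00206 to 0.166 for ILC3, 0.79 to 0.969 for survival and -0.02 to 0.02 for the log2 fold change of Maf, with changes of sign for survival and Maf.

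The replicate numbers were not taken as pairs, since the labels do not say what they mark. Libraries that share a number did not deviate together (correlations of -0.048, -0.023 and -0.03, and at most 0.028 with another number). These correlations weighted all tested genes alike, so counting error in genes of low level may hide a pairing. With the replicate block 5817 genes changed, 580 of them 2-fold, and the immediate early list moved to 0.0542. Counting error weighs most in genes of low level, and 491 of the 610 changes of 2-fold lie in genes under 5 CPM in the higher group.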

Other observations

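The tests of circadian genes, of immunoglobulin genes and of the neighbours of Il10, the test for a lower share of ILC2s, and the values given for ILC2s that express T-cell genes and for more cycling cells were chosen after the results were seen; what the other tests below should give was written down before their results, although the centring of the GC and length correction came after its first result. Clock-controlled genes, which form or follow the circadian oscillator, were lower in the IL-10-producing libraries. Of 17 tested, 14 fell and 1 rose (median log2 fold change -0.41, camera p = 1.41e-06, and p = 0.00653 with an estimated correlation), and 4 of them are also in the fixed lists. Nr1d1, which encodes the repressor REV-ERBα, fell from 9.29 ± 0.595 to 2.79 ± 0.671 CPM, Npas2 from 7.56 ± 0.629 to 3.10 ± 0.177 CPM, Per3 from 7.49 ± 0.241 to 3.58 ± 0.256 CPM and Arntl, which encodes BMAL1, from 33.3 ± 1.24 to 26.3 ± 0.634 CPM (SD, n = 3). Nfil3 was the gene that rose. Clock stood at 55.3 ± 1.97 against 53.7 ± 1.04 CPM and did not pass (edgeR adjusted p = 0.402). Markers of T cells (14 of 14 lower, median -2.67) and of granulocytes, basophils and mast cells (11 of 13 lower, median -2.37) fell in the same libraries.

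Immunoglobulin genes were higher in the IL-10-producing libraries, at low levels. Whether the transcripts came from ILC2s or from a few B-lineage cells in that gate was not tested. Of 12 B-cell markers, 3 were higher and 7 lower in the same libraries. The 3 higher ones were Igkc and Ighm, which are immunoglobulin genes themselves, and Fcmr, a neighbour of Il10 given below. Of 14 immunoglobulin genes tested, 12 rose and 0 fell (camera p = 1.49e-09, and p = 0.00301 with an estimated correlation), and 3 of the 14 are also in the fixed lists. Igkc rose from 2.00 ± 0.120 to 6.38 ± 0.587 CPM. Jchain, the joining chain of secreted antibodies, is not among these 14 genes and rose from 0.152 ± 0.0377 to 1.73 ± 0.303 CPM. Around Il10, the tested neighbours within 250 kb included Il24, Fcmr, Mapkapk2, Dyrk3, Eif2d and Rassf5, which rose by 1.60, 0.91, 0.31, 0.39, 0.16 and 0.18 on the log2 scale, and Ikbke, which fell by 0.26. Whether neighbours of Il10 rise more than genes elsewhere was not tested.

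The real split of the libraries gave 5943 changed genes, 610 of them 2-fold, and 12 lists past camera. It was the 1 split of 10 with values that large in each case, and the highest other split gave 0, 0 and 6. With 10 splits a share under 0.05 cannot be reached. The other splits called 4 to 6 lists although none of them called a gene. Camera with the preset correlation can thus call lists where no gene passes. Each of these splits put libraries of both populations on both sides. Part of the real difference stayed between the sides, and the rest widened the spread within them. Their counts of genes and lists therefore do not show what libraries without a real difference would give.

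The libraries of a group differed by very little, with a biological coefficient of variation of 2.81%, and this small spread is part of why changes of a few percent passed the test. If the libraries of a group came from different mice, the few T-cell and B-cell receptor variable genes present would be expected to differ between them, provided their transcripts were rearranged, which was not tested. Over 23 such genes the median ratio of variance to mean within a group was 1.73, between the 5th and 95th percentiles (1.06 and 2.37) of 10000 sets of other genes at the same counts. Single values ran from 0.0117 (Trbv3, IL-10-negative) to 12 (Igkv14-126, IL-10-producing). No libraries known to come from separate mice were at hand, so the median cannot tell these from a common pool of cells or RNA. A common pool stays possible, and the p-values would then not extend to other mice. GC content and transcript length as the cause of the changed genes is argued against by the corrected fit, in which 6025 genes changed.

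T-cell transcripts were higher in IL-10-negative libraries. If T cells among the sorted IL-10-negative cells were the source, receptor variable genes, which were not among the markers, would be higher there as well. Of the 13 tested, 76.9% were (10 genes). The summed level of all 13 was 6.60 ± 0.809 CPM in IL-10-negative against 2.03 ± 0.349 CPM in IL-10-producing libraries. A few T cells in that gate may thus explain the lower Cd8a, Cd3e and Cd8b1 in IL-10-producing cells; the markers that define the gate were not given in the sources used here. Whether the variable gene transcripts were rearranged or germline was not tested, and Trdv4 did not differ past the threshold (1.12 ± 0.369 against 0.978 ± 0.432 CPM, edgeR adjusted p = 0.646). ILC2s in the IL-10-negative gate that express these genes themselves cannot be told apart from this by the median of the markers (-2.67), since each library is a mixture of cells.

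Cell-cycle genes were higher in IL-10-producing libraries. A lower share of ILC2s among the IL-10-negative cells would lift ILC2 genes in the same direction. Of the ILC2 identity genes 6 did rise, among them Arg1, Klrg1 and Il2ra by 0.66, 0.63 and 0.47 on the log2 scale. Another 12 besides Tcf7 were lower in IL-10-producing cells, but this was known when the test was chosen. A lower share alone would give these falls only if the other cells hold more of these transcripts, which was not tested. A lower share of ILC2s is therefore not decided. GC content and transcript length are argued against, since the median of the mitosis list was 0.34 after the correction. More cycling cells in the IL-10-producing population (median 0.317) and more transcripts per cycling cell cannot be told apart without data on single cells, and both stay open as hypotheses.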
